A study of Sebastes mystinus with 44 samples.

How the data were processed

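White muscle RNA of juvenile blue rockfish (Sebastes mystinus) was measured by sequencing of 44 libraries, each from a different fish, in 12 groups made of 4 exposures and 3 sampling times. Per the labels, fish lived in aquaria with flowing seawater, and pH and oxygen were lowered by bubbling carbon dioxide and nitrogen. The exposures are named control, pH, DO and cross. The labels do not define cross, which from what is known of the study is the combined exposure. Each group held 4 fish, except pH and DO at 24 h with 3 fish each and pH at 2 weeks with 2 fish. The aquarium and library preparation set of each fish are not given in the sources used here, so neither could enter a model, and fish of 1 group may share an aquarium. At all 3 times cross fish carry numbers from 7064 to 7079, and all other fish numbers from 13 to 60. Whether cross fish were obtained or handled separately is not known. Any such difference cannot be told apart from the exposure in comparisons with cross or in the non-additive part. P-values treat fish as independent samples.

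Per the labels' protocols, libraries were stranded mRNA libraries prepared in sets with randomized order. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic 0.36, RSEM 1.3.0, Bowtie and edgeR were used, with no order or role given. The deposited tables, 1 per sampling time, hold expected counts (estimated reads per assembled feature, as RSEM gives them), not normalized, and 9.60% of their values are not whole numbers. The 239549 features carry Trinity gene identifiers, so they come from a de novo assembly, whose settings are not given in the sources used here. The tables pair no feature with a gene name. The gene lists fixed in advance (camera tests of pathways and cell type markers) were therefore not run. Several features can come from 1 gene, and reads shared between near-identical assembled copies may have been split among them.

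Expected counts were rounded to whole numbers. Of the 239549 features, 84427 were at 0 in every library. Totals ran from 9885000 to 36693000 counts per library (median 15332000), so 3 counts corresponded to 0.0818 to 0.303 CPM (counts relative to the library total), the lowest level that the depth of each library resolves, counting error only. The chi-square statistic per feature in the 61 pairs of fish from the same group ran from 33.4 to 271, far above sampling noise, so within groups no library was a copy of another. Pairs of different groups were not compared in this way.

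Tests were made in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (robust, TMM scaling, filterByExpr with a minimum count of 10 and total of 15), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All groups of a sampling time entered 1 fit, with 24701 features tested at 12 h, 26357 at 24 h and 26595 at 2 weeks. Comparisons were pH, DO and cross against control, cross against pH and DO, and the non-additive part (cross minus pH minus DO plus control, log2 scale). Comparisons across times used 1 fit of all 44 libraries with 12 groups and 34070 features. CPM values are scaled by TMM. Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. Log CPM values used a prior count of 2.

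Named features follow a rule fixed before the data were examined, as do the tests and the main alternatives. Without gene names, up to 2 features that rose and 2 that fell per comparison with control were named, those with the largest fold change past the threshold, with average log2 CPM of at least 1 and every exposed fish on the same side of the control mean. The same rule was applied to the control fish across times after the values were seen. Other named features were chosen after their values were seen.

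Alternatives were RLE size factors, no low-count filter, a stricter filter (minimum count 30), DESeq2 1.42.0, limma 3.58.1 voom with quality weights, 1 surrogate variable (sva 3.50.0), a fit of only the groups compared, and each fish left out in turn. Across times, size factors, filters and fish left out were varied. Fold changes of exposures that share controls were compared with 20 simulated sets of unchanged groups and with the controls split into 2 and 2 fish. Single values were tested by exact permutation or by 100000 permutations, and distances between fish by 10000.

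The edgeR test was tested on simulated data drawn from the real means and library sizes, with 200 features changed, 100 of them 2-fold and 100 of them 4-fold. At 12 h (24701 features simulated), pH, DO and cross against control recovered 4%, 4% and 3% of 2-fold changes and 54%, 51% and 48% of 4-fold changes. At 24 h (26357 features) the recovered shares were 0%, 0% and 2% of 2-fold changes and 23%, 15% and 32% of 4-fold changes. At 2 weeks (26595 features) they were 1%, 16% and 13% of 2-fold changes and 44%, 54% and 66% of 4-fold changes. For controls at 2 weeks against 12 h (34070 features) they were 8% and 38%. Most 2-fold changes were therefore missed in every comparison simulated, and most 4-fold changes in all 3 at 24 h, in cross at 12 h, in pH at 2 weeks and in controls.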

Results

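White muscle of juvenile blue rockfish was sampled after 12 h, 24 h and 2 weeks in control seawater, in seawater of lowered pH (high pCO2, group pH), in seawater of lowered oxygen (group DO) and in the group named cross, to ask how muscle gene expression responds to these exposures and how the response depends on time. The 44 libraries held between 9885000 and 36693000 counts. Between 39095 and 76543 features had a count in a library, and the 100 most abundant features took 42.1% to 64.9% of all counts. Fish of the same group were hardly more alike than fish of different groups. The mean correlation of log2 CPM was 0.921 within groups and 0.919 between groups at 12 h, 0.902 and 0.900 at 24 h, and 0.934 and 0.928 at 2 weeks. The biological coefficient of variation was 40.4% at 12 h, 47.8% at 24 h and 34.6% at 2 weeks.

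**Figure D1:**
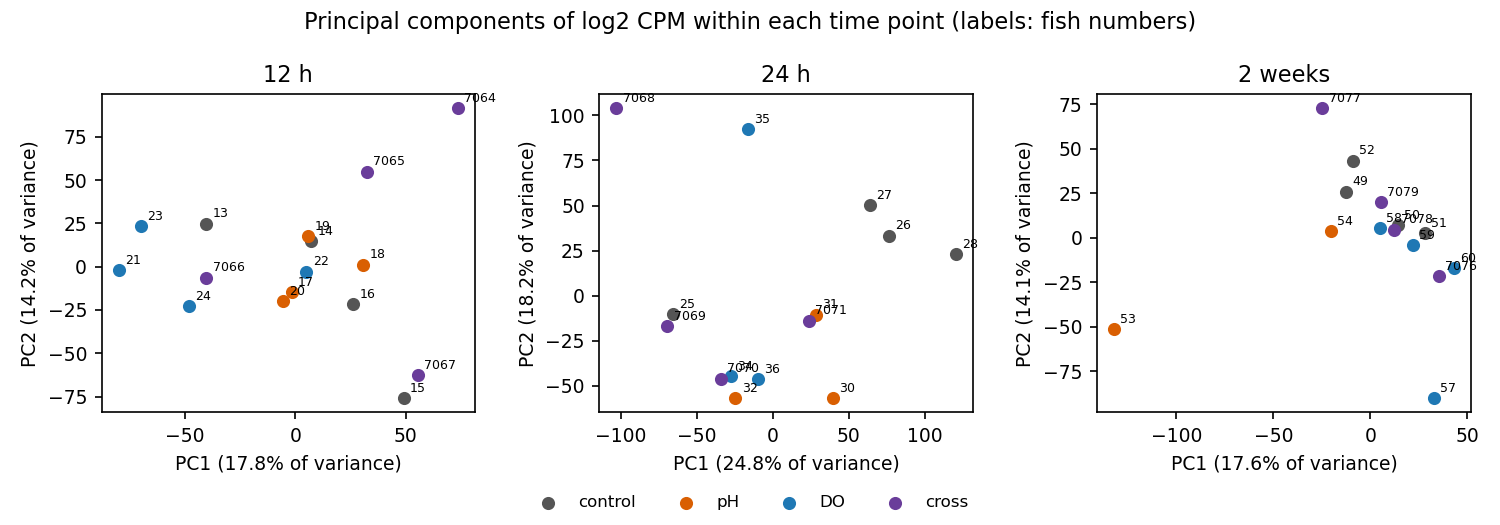
Each point is a fish, placed by the first and second principal components (PC1, PC2) of log2 CPM within its sampling time and coloured by exposure, with fish numbers (the labels' Mys numbers) beside the points. PC1 held 17.8% of the variance at 12 h, 24.8% at 24 h and 17.6% at 2 weeks, where pH fish Mys53 lay far from the other 13 fish.

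At 12 h no feature passed the edgeR test between exposed and control fish (n = 4 per group). edgeR called 0 features for pH, with 526 of 24701 at an unadjusted p under 0.05 where chance gives 1235. DESeq2 called 7 and limma voom 0. For DO edgeR called 0, with 1635 at an unadjusted p under 0.05, against 29 by DESeq2 and 0 by voom. For cross it called 0, with 1229 at an unadjusted p under 0.05, and DESeq2 and voom both called 0. The median absolute log2 fold change was 0.22 for pH, 0.30 for DO and 0.28 for cross. Single fish moved the called counts a little: pH gave 2 features without control fish Mys13 and DO gave 2 without DO fish Mys22. The count at an unadjusted p under 0.05 moved more, for pH to 814 without pH fish Mys19, and for cross to 2376 without cross fish Mys7067, 2344 without fish Mys7066 and 711 without fish Mys7064.

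Between cross and DO fish at 12 h edgeR called 0 features (smallest adjusted p 0.125), with 2774 at an unadjusted p under 0.05, DESeq2 240 and voom 0. Without cross fish Mys7066 edgeR called 329 features, and without DO fish Mys22 it called 1. Cross against pH gave 0 features in edgeR (1090 at an unadjusted p under 0.05), 15 in DESeq2 and 0 in voom. The non-additive part gave 0 in edgeR (1591 at an unadjusted p under 0.05), 12 in DESeq2 and 0 in voom, and 3 in edgeR without cross fish Mys7066. Without that fish the counts at an unadjusted p under 0.05 were 4335 for cross against DO, 2283 for cross against pH and 2795 for the non-additive part. For cross against pH they were 1887 without cross fish Mys7067 and 546 without cross fish Mys7064.

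At 24 h cross and control fish did not differ beyond the spread between fish in the edgeR test. edgeR called 0 features, with 4211 of 26357 at an unadjusted p under 0.05 where chance gives 1318 (smallest adjusted p 0.199) and 1609 with 1 surrogate variable, while DESeq2 called 540 (190 rose, 350 fell) and voom 1027 (254 rose, 773 fell). The outcome depended on control fish Mys25: without it edgeR called 1019 features, and without any other fish of these groups 0. Voom gave fish Mys25 a quality weight of 0.302, the lowest at 24 h. The voom count is therefore not independent of the edgeR count without this fish. The pH comparison (3 against 4 fish) gave 0 features in edgeR, with 2199 at an unadjusted p under 0.05, 26 in DESeq2, 0 in voom, and 1 in edgeR without pH fish Mys31. The DO comparison (3 against 4 fish) gave 0 features in edgeR, DESeq2 and voom. At an unadjusted p under 0.05 it had 1709 in edgeR, 835 with 1 surrogate variable and 5359 in voom. Without control fish Mys25 the counts at an unadjusted p under 0.05 were 6317 for cross, 3638 for pH and 3781 for DO. Without control fish Mys28 they were 2668 for cross and 965 for DO, and without pH fish Mys32 the pH count was 1235.

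Between exposures at 24 h edgeR called 0 features for cross against pH (1783 at an unadjusted p under 0.05; DESeq2 5, voom 0) and 0 for cross against DO (753; DESeq2 4, voom 1). Without pH fish Mys31 the former gave 1 feature, and without cross fish Mys7068 the latter gave 1. The non-additive part gave 0 features in edgeR, DESeq2 and voom, with 1104 at an unadjusted p under 0.05. The unadjusted count for cross against pH was 1120 without pH fish Mys30, 857 without cross fish Mys7068 and 2946 without cross fish Mys7071. For cross against DO it was 1173 without DO fish Mys35, 462 without cross fish Mys7069 and 1305 without cross fish Mys7071. For the non-additive part it was 1830 without control fish Mys25, 2395 without DO fish Mys35 and 610 without DO fish Mys36.

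After 2 weeks 1 feature was higher in fish under lowered oxygen than in controls. TRINITY_DN45419_c4_g1 stood at 22.8 ± 4.80 CPM (SD, n = 4) in DO fish and 4.68 ± 1.07 CPM (SD, n = 4) in control fish, a log2 fold change of 2.28 (SE 0.23, edgeR adjusted p = 0.000415). It was the only feature that edgeR called for DO, with 2123 of 26595 at an unadjusted p under 0.05 where chance gives 1330. That count was 1373 without control fish Mys52 and 1298 with 1 surrogate variable. DESeq2 called 34 features and voom 1. TRINITY_DN45419_c4_g1 passed the edgeR test with each of the 8 fish left out, with log2 fold changes from 2.13 to 2.44 and adjusted p up to 0.00555.

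TRINITY_DN45419_c4_g1 was not raised in the same way where cross was applied. Cross fish had 5.32 ± 1.04 CPM (SD, n = 4), lower than DO fish by a log2 fold change of -2.09 (SE 0.23, edgeR adjusted p = 0.00134), and this was the 1 feature that edgeR called for cross against DO (1881 at an unadjusted p under 0.05; DESeq2 63, voom 1). When only these groups entered the fit, edgeR called 16 features. The pH fish had 11.6 ± 2.88 CPM (SD, n = 2). At the earlier times DO fish had 12.7 ± 7.79 CPM (SD, n = 4) at 12 h and 4.09 ± 1.64 CPM (SD, n = 3) at 24 h, beside control values of 5.81 ± 3.08 CPM (SD, n = 4) and 3.60 ± 1.103 CPM (SD, n = 4), scaled over all 44 libraries. The dependence of its DO effect on time had an edgeR p of 0.0160, adjusted p 0.661 over all features and 0.0160 over the 3 features named for exposures. These 3 were chosen by their calls at 2 weeks, so the smaller adjustment is too favourable and no dependence on time is claimed.

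**Figure D2:**
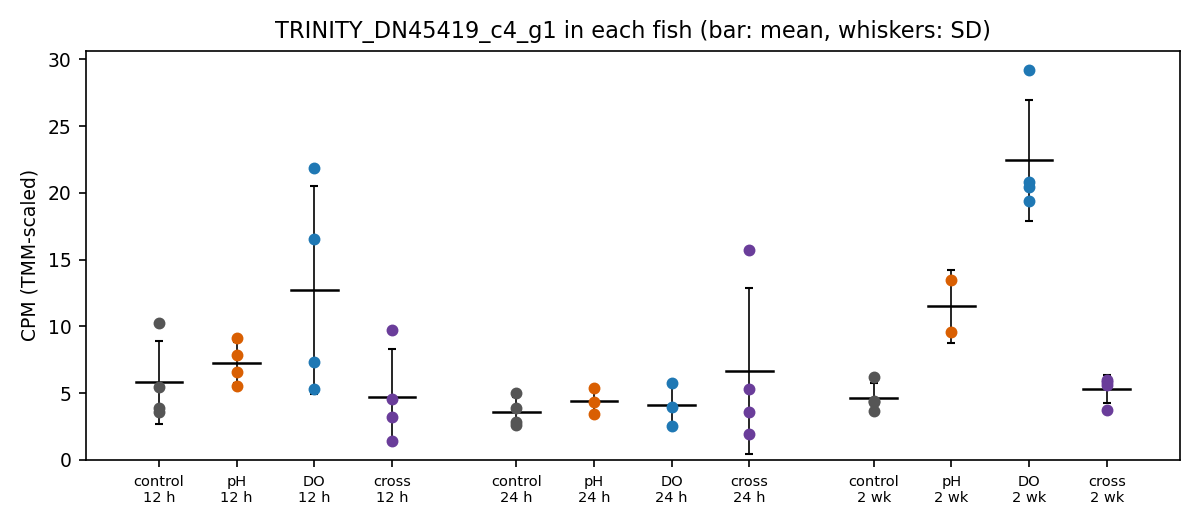
CPM of TRINITY_DN45419_c4_g1 in each fish (vertical axis, scaled over all 44 libraries) by exposure and sampling time (horizontal axis). Points are fish, bars are group means and whiskers are SD. The 4 DO fish at 2 weeks lie between 19.4 and 29.2 CPM, above all other fish sampled at 2 weeks.

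In the pH group at 2 weeks 33 features differed from controls, 32 higher and 1 lower, and this count rested on single fish (n = 2 against 4). TRINITY_DN41598_c1_g1 stood at 28.3 ± 20.1 CPM (SD, n = 2) in pH fish and 3.22 ± 1.43 CPM (SD, n = 4) in controls, a log2 fold change of 3.14 (SE 0.52, edgeR adjusted p = 0.0397). TRINITY_DN49254_c5_g1 stood at 2084 ± 1665 CPM and 352 ± 34.9 CPM, a log2 fold change of 2.56 (SE 0.39, edgeR adjusted p = 0.0397). The feature that fell, TRINITY_DN42171_c1_g4, is outside the naming rule for its low level and was chosen after its value was seen. It had 2 counts over both pH fish and 125 counts over the 4 control fish, a ratio of 17.4 in favour of controls (95% interval 4.71 to 145, exact binomial, counting error only).

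Without pH fish Mys54 edgeR called 933 features for pH against control at 2 weeks, and without pH fish Mys53 or any of control fish Mys49, Mys50, Mys51 and Mys52 it called 0; a lone pH fish is there assumed to vary like the other groups. The full fit had 3296 features at an unadjusted p under 0.05 (1360 without fish Mys53, 5086 without fish Mys54), DESeq2 called 755 features, voom and the fit with 1 surrogate variable 0, and the fit of only these groups 1. Over the 33 called features the median log2 shift from the control mean, in the called direction, was 2.31 in fish Mys53 and 0.88 in fish Mys54. The log2 fold change of TRINITY_DN41598_c1_g1 was 2.16 without fish Mys53 and 3.72 without fish Mys54, and that of TRINITY_DN49254_c5_g1 was 1.38 and 3.19. Both named features that rose lost the call under voom, the surrogate variable and the fit of only these groups, with adjusted p up to 0.179 and 0.156, while their log2 fold changes there were 3.16 to 3.19 and 2.45 to 2.59. TRINITY_DN42171_c1_g4 lost its pH call in these 3 fits and with each of the 6 fish left out, and DESeq2 gave it no adjusted p. Its log2 fold change stayed between -4.12 and -3.52 over the alternatives, and was -3.60 without fish Mys54 and -4.39 without fish Mys53. The dependence on time of the pH effect had edgeR adjusted p of 0.412 and 0.511 over all features for the 2 that rose (0.00635 and 0.0151 over the 3 named, which were chosen by their calls at 2 weeks).

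No feature separated cross from control fish at 2 weeks in the edgeR test (n = 4 each). edgeR called 0 features, with 1172 at an unadjusted p under 0.05 where chance gives 1330, DESeq2 called 1 and voom 0. With each fish left out in turn edgeR also called 0, without control fish Mys50 698 features had an unadjusted p under 0.05, and the median absolute log2 fold change was 0.24. Cross against pH gave 0 features in edgeR (3449 at an unadjusted p under 0.05, smallest adjusted p 0.0821), 747 in DESeq2, 0 in voom, 2 in the fit of only these groups and 774 in edgeR without pH fish Mys54. Without pH fish Mys53 its count at an unadjusted p under 0.05 was 1434.

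A non-additive change was called for 3 features at 2 weeks, all named here after their values were seen. TRINITY_DN45419_c4_g1 was lower in cross fish than the sum of the pH and DO effects gives, by a log2 value of -3.39 (SE 0.35, edgeR adjusted p = 0.000540). TRINITY_DN44190_c12_g4, at 71.0 ± 34.4 CPM (SD, n = 2) in pH fish and 22.5 ± 2.91 CPM (SD, n = 4) in controls, was lower than additive by -2.18 (SE 0.33, edgeR adjusted p = 0.0382). TRINITY_DN42171_c1_g4 was higher than additive by 5.31 (SE 0.79, edgeR adjusted p = 0.0382), with 2 counts in the pH fish. TRINITY_DN45419_c4_g1 passed with each of the 14 fish left out, with adjusted p up to 0.0116, whereas the calls of TRINITY_DN44190_c12_g4 and TRINITY_DN42171_c1_g4 were lost in 11 and 10 of these 14 fits, and the value of TRINITY_DN44190_c12_g4 was -1.57 without pH fish Mys53. The full fit had 3112 features at an unadjusted p under 0.05 (1732 without pH fish Mys53, 4708 without pH fish Mys54), DESeq2 called 670 features and voom 1. edgeR called 766 without pH fish Mys54, 9 without control fish Mys50, 5 without control fish Mys49, and 1 without any of fish Mys51, Mys52, Mys53, Mys57, Mys58, Mys59, Mys60, Mys7076, Mys7077 and Mys7078.

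Sampling time separated the fish. Time accounted for 21.2% of the squared distances between the 44 fish, where chance gives 4.65% (permutation p = 1e-04 within exposures, the smallest that 10000 permutations can give). Control fish at 2 weeks differed from control fish at 12 h in 4801 of 34070 features, 1916 higher and 2885 lower (n = 4 each, edgeR), with 9476 at an unadjusted p under 0.05 where chance gives 1704. The tables were deposited per time, and library preparation sets are not known by fish, so time and any handling that went with it cannot be told apart.

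Among features higher in control fish at 2 weeks, TRINITY_DN55112_c3_g1 stood at 245 ± 270 CPM (SD, n = 4) against 7.20 ± 3.37 CPM (SD, n = 4) at 12 h, a log2 fold change of 5.09 (SE 1.20, edgeR adjusted p = 0.00446), and of 4.45 without control fish Mys49. TRINITY_DN45128_c3_g1 stood at 148 ± 78.9 CPM against 1.99 ± 1.55 CPM (SD, n = 4 each), a log2 fold change of 6.18 (SE 1.93, edgeR adjusted p = 0.0287), and its call was lost with 3 of the 8 fish left out. Without control fish Mys14 its log2 fold change was 6.88. Its level was 68.2 CPM or more in 13 of all 44 fish and 4.22 CPM or less in the other 31. Among features lower at 2 weeks, TRINITY_DN50832_c5_g5 had 3 counts over the control fish at 2 weeks and 450 at 12 h, a ratio of 196 (95% interval 66.6 to 953, exact binomial, counting error only). TRINITY_DN55997_c3_g3 had 1 count and 321 counts, a ratio of 419 (95% interval 74.7 to 16610). Without control fish Mys15, Mys16 or Mys52 the number of changed features was 2849, 2953 and 3074.

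Exposed fish moved the same way. Of the 4801 features, 4752 (99.0%) had a difference of the same sign between exposed fish at 2 weeks and at 12 h (n = 10 and 12). A score averaging the 4801 features in the direction seen in controls rose by 1.61 log2 units in controls and by 1.00 in exposed fish (permutation p = 1e-05, the smallest that 100000 permutations can give). The rise was 1.33 in pH, 0.66 in DO and 1.09 in cross fish. All 10 exposed fish at 2 weeks scored above all 12 exposed fish at 12 h. With the mean over the 4 exposures in place of controls, chosen after seeing the data, edgeR called 10897 features between 12 h and 2 weeks.

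**Figure D3:**
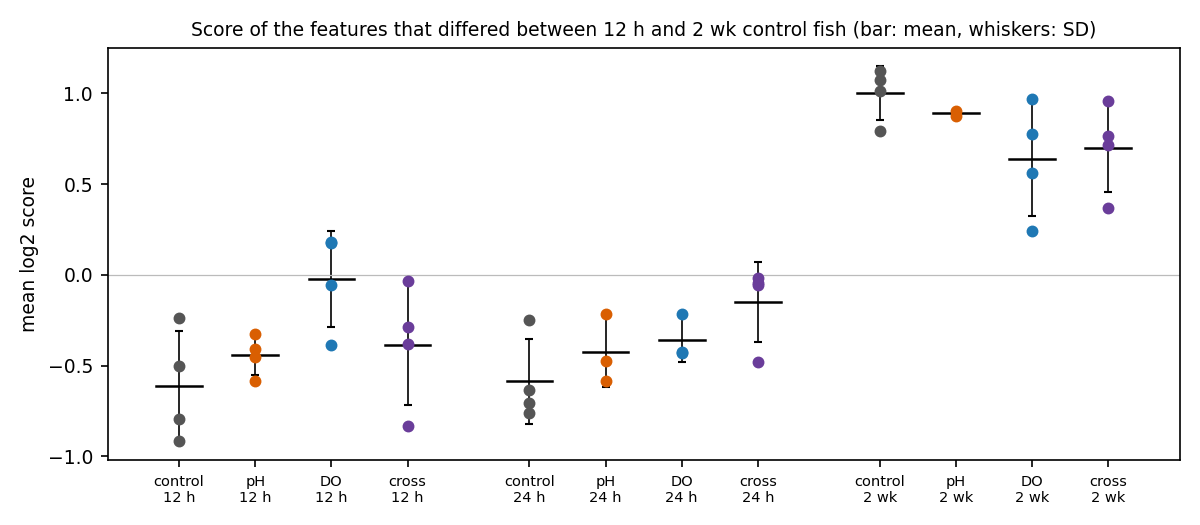
Mean log2 score of the 4801 features that differed between control fish at 12 h and 2 weeks (vertical axis) by exposure and sampling time (horizontal axis). Points are fish, bars are group means and whiskers are SD. Exposed fish averaged -0.28 at 12 h, -0.29 at 24 h and 0.71 at 2 weeks.

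Between 12 h and 24 h control fish differed in 340 features, 182 higher and 158 lower at 24 h (n = 4 each, edgeR), with 4888 at an unadjusted p under 0.05. TRINITY_DN44170_c1_g1 fell from 142 ± 55.8 to 5.62 ± 2.59 CPM (SD, n = 4), a log2 fold change of -4.66 (SE 0.89, edgeR adjusted p = 0.01001), a call lost without control fish Mys28 (adjusted p 0.0852). TRINITY_DN49088_c3_g2 fell from 3.56 ± 0.940 to 0.145 ± 0.0533 CPM (SD, n = 4), a log2 fold change of -4.51 (SE 0.78, edgeR adjusted p = 0.00344), and passed with each of the 8 fish left out. TRINITY_DN44262_c3_g2 rose by 3.52 (SE 0.84, edgeR adjusted p = 0.0329) and TRINITY_DN50328_c5_g1 by 3.03 (SE 0.73, edgeR adjusted p = 0.0335) on the log2 scale, calls lost in 7 and 6 of these 8 fits. Without control fish Mys28 the log2 fold change of TRINITY_DN50328_c5_g1 was 2.33. The count moved with single fish, to 2094 without control fish Mys25, 154 without fish Mys16, 114 without fish Mys26, 70 without fish Mys27, 38 without fish Mys14, 21 without fish Mys13 and 12 without fish Mys28. With the mean over the 4 exposures in place of controls, chosen after seeing the data, edgeR called 2623 features.

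Whether an exposure effect changed between times was tested directly. edgeR called 0 features for pH (2670 of 34070 at an unadjusted p under 0.05, where chance gives 1704), 0 for DO (2388) and 0 for cross (4540, smallest adjusted p 0.123); no other tool was run for these tests. Without control fish Mys25 it called 12, 5 and 985 features (DO 3776 at an unadjusted p under 0.05), without pH fish Mys54 it called 7 for pH, and for cross it called 81 without cross fish Mys7071, 79 without cross fish Mys7066 and 1 without cross fish Mys7064.

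The pH, DO and cross fold changes of a time correlated across features, as comparisons that share controls do. The correlation ran from 0.27 to 0.46 at 12 h, 0.58 to 0.73 at 24 h and 0.27 to 0.47 at 2 weeks, where simulated unchanged groups gave 0.51 to 0.52, 0.41 to 0.46 and 0.35 to 0.48 (features are not independent replicates). The highest, DO with cross at 24 h, was 0.73 (jackknife SE 0.17) with a covariance of 0.31 beside a simulated 0.14. With separate control fish the correlation fell to 0.30 and the covariance was 0.16 (permutation p of this covariance = 0.0437, adjusted over 9 pairs 0.393). No pair passed adjustment.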

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

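The score test of the 24 h difference at other times, the comparison of both directions of change in fish Mys53, and the bound used for the control fish at 12 h and 2 weeks, were chosen after the results were seen. For each result, other splits of the same fish were counted to ask whether fish grouped at random give as much.

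Of 67 sets of 4 fish tested for a fish far from the other 3, 9 held one, where chance gives 3.35. Total counts were 16934130 in control fish Mys14 at 12 h (others up to 12952496), 36692935 in pH fish Mys19 at 12 h (others up to 18303655) and 12930085 in cross fish Mys7071 at 24 h (others from 14390363). The TMM factor was 1.03 in control fish Mys49 at 2 weeks (others from 1.20), and the 100 most abundant features took 53.6% of counts in cross fish Mys7076 at 2 weeks (others from 59.7%). TRINITY_DN45419_c4_g1 was at 29.2 CPM in DO fish Mys57 (others 19.4 to 20.8) and at 3.74 CPM in cross fish Mys7077 (others 5.63 to 5.99), both at 2 weeks. Control fish Mys51 at 2 weeks had 0.0530 CPM of TRINITY_DN55997_c3_g3 and 0.159 CPM of TRINITY_DN50832_c5_g5, where the other 3 had 0. With 3 fish at 0 any count in the remaining fish is flagged, so these sets are no evidence of more outliers than chance gives. At 2 weeks the non-additive part was called by edgeR at log2 values of -3.39 for TRINITY_DN45419_c4_g1, 5.31 for TRINITY_DN42171_c1_g4 and -2.18 for TRINITY_DN44190_c12_g4. If cross is the combined exposure, this part is the difference of the oxygen effect with and without lowered pH. It rests on 2 pH fish. The calls of TRINITY_DN42171_c1_g4 and TRINITY_DN44190_c12_g4 were lost in 10 and 11 of 14 fits with a fish left out.

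In the splits, the statistic was the number of features past adjustment, or the number at an unadjusted p under 0.05 where the real split gave 0 past adjustment, since 0 is matched by every split. Of the results split, chance was argued against only for controls at 2 weeks against 12 h, where 1 of 21 splits, the real one, gave as many (4801, highest other 4). The 21 were a random part of the possible splits, and 1 of 21 is the smallest share they can give. No adjustment over the results split was made, and splits of fish do not address a shared aquarium. For controls at 24 h against 12 h 2 of 21 splits gave as many (340, highest other 1052, a split that joined control fish Mys25 with 12 h fish Mys13, Mys14 and Mys15). For DO against control at 2 weeks 3 of 35 did (1, highest other 2), and for cross against DO 2 of 35 (1, highest other 1), so for the number of features chance is not excluded. A count of 1 is matched by any split with a call, so these splits do not test TRINITY_DN45419_c4_g1 itself (adjusted p 0.000415 for DO against control, called in all 7 alternatives and with each of the 8 fish left out). At 2 weeks cross against control gave 12 of 35 (1172, highest other 2397).

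At 12 h 32 of 35 splits gave as many features as pH against control (526, highest other 1738), 5 as DO against control (1635, highest other 3069), 23 as cross against control (1229, highest other 4100), 23 as cross against pH (1090, highest other 3037), 2 as cross against DO (2774, highest other 5102) and 22 of 100 as the non-additive part (1591, highest other 3152). At 24 h 5 of 35 splits gave as many as pH against control (2199, highest other 4475), 9 as DO against control (1709, highest other 5601), 3 as cross against control (4211, highest other 7634), 10 as cross against pH (1783, highest other 3719), 26 as cross against DO (753, highest other 4223) and 46 of 100 as the non-additive part (1104, highest other 5779). For effects that differ between times 8 of 21 splits gave as many for DO (2388, highest other 8366) and 2 of 21 for cross (4540, highest other 8411). These splits shuffled sampling times within the exposure and within the controls. The large difference between times enters such splits and can raise their counts, so they cannot judge chance for these effects. In cross against control at 24 h, the split that put control fish Mys25 with cross fish Mys7068, Mys7069 and Mys7070 called 2723 features after adjustment where the real split called 0. It exchanges only fish Mys25 and Mys7071, and so many calls point to a structure of these fish, of which the source was not tested. Comparisons with the 2 pH fish at 2 weeks, and with them the pH effect across times, were not split.

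Cross against control at 24 h had 0 features past adjustment with all fish and 1019 without control fish Mys25. An exposure response shared with other times was examined by a score of the 1000 features with the largest control difference at 24 h. It differed between all controls and all exposed fish by 1.65 log2 units at 24 h, a size that follows from the choice of features. At 12 h and 2 weeks it differed by 0.0230 (SE 0.104, permutation p = 0.863), so this set showed no such difference there. The score pools pH, DO and cross fish and was not made from the 1019 features. A cross response shared with other times therefore stays open, as does a response seen at 24 h alone. Greater depth of fish Mys25 is argued against, since thinning it to 13032000 counts left 0 features past adjustment. A wrong label of fish Mys25 stays open: it correlated better with DO fish (0.909) than with the other controls (0.860), but 8 of the other 13 fish also correlated better with another group. The bound set in advance would have excluded a wrong label on that count of 8, but fish that sit near other groups do not forbid it.

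The features called at 2 weeks with fish Mys53 as the only pH fish (933) are the second pattern. RLE size factors gave 1021 features but changed the size of this library by only -0.06 log2 units, so they do not test its scaling. Scaling is argued against as the cause of both directions of change, since 659 features rose and 274 fell and 1 factor moves all features alike. The 2 sets lay 2.36 log2 units apart, although a distance is expected of features chosen by their calls. Scaling is left open for either direction alone. A response of both pH fish is a candidate explanation, since fish Mys54 moved by a median of 0.42 log2 units in the direction of fish Mys53 (1.59), beyond the 0.05 to 0.39 of the 8 DO and cross fish, by a margin within the spread of those 8. Library make-up is a candidate explanation as well: over the 30 fish of 12 h and 24 h the score of these features followed the share of counts in the 100 most abundant features (Pearson r = 0.619, permutation p = 0.00025; Spearman rho = 0.638, permutation p = 0.00021; r = 0.529 without the 2 most extreme fish; r = 0.411 at 12 h and 0.741 at 24 h). Features of the score that were among these 100 were not removed, so part of the correlation may be built in. Fish Mys53 itself had the highest share of counts in the 100 most abundant features of all libraries (64.9%). It also had the lowest TMM factor (0.575) and the fewest features with a count (39095). Fish Mys54 had 55.8%, 0.983 and 46324. With 2 pH fish these explanations stay open together.

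The difference between control fish at 12 h and 2 weeks is the third pattern. A difference limited to these 8 control fish or their aquaria is argued against, since exposed fish showed 0.618 (SE 0.0727) of it (permutation p = 1e-05, the smallest possible). The SE takes the control difference as fixed and leaves out the spread of the control fish. The bound set in advance, that every exposure exceed 0.5, was missed by DO at 0.410. The bound used, more than 0.25 by 2 SE, was chosen after these values were seen. Time of day is argued against as the cause of the mean score difference. Exposed fish at 24 h lay at -0.0117 (SE 0.114) of the way from 12 h to 2 weeks. They share a clock time with the 2 week fish if sampling kept to it. The score averages over all these features, so time of day stays open for single features. Library make-up is argued against for the exposed fish, since the share of the 100 most abundant features accounted for 0.00850 of their score difference. The same was not computed for the control fish. Time in captivity, growth, feeding or a batch of handling that went with time may each contribute, were not tested and stay open.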

How the results depend on the processing

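The mean over exposures in place of controls was chosen after seeing the data; all other alternatives were set in advance, and the cause of each move below was not tested unless stated. No paired analysis was possible because each fish number occurs in 1 group only. The gene list tests were not run, since the tables hold no gene names. RLE size factors kept all 23 counts within 1.5 times. TRINITY_DN45419_c4_g1 kept its DO call at 2 weeks under all 7 alternatives (log2 2.02 to 2.29, adjusted p up to 0.00679). Without a low-count filter the calls of TRINITY_DN45128_c3_g1, TRINITY_DN44262_c3_g2 and TRINITY_DN50328_c5_g1 were lost (adjusted p 0.109, 0.0971 and 0.0998). The non-additive calls of TRINITY_DN42171_c1_g4 and TRINITY_DN44190_c12_g4 were lost under the stricter filter and voom, and that of TRINITY_DN42171_c1_g4 also in DESeq2. Depth limits features near 0.3 CPM. In simulated data the exposure tests called 0% to 16% of 2-fold changes, and at 24 h 15% to 32% of 4-fold changes, so counts of 0 at 24 h leave 4-fold changes open.

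Without a low-count filter the counts at 12 h for pH, DO, cross, cross against pH, cross against DO and the non-additive part were 30, 154, 83, 104, 566 and 135, at 24 h 145, 126, 1084, 195, 45 and 40, and at 2 weeks 560, 189, 70, 478, 180 and 532; for pH, DO and cross effects that differ between times they were 68, 85 and 515. DESeq2 gave 7 (pH), 29 (DO), 15 (cross against pH), 240 (cross against DO) and 12 (non-additive) at 12 h, 26 (pH), 540 (cross), 5 (cross against pH) and 4 (cross against DO) at 24 h, and 755, 34, 1, 747, 63 and 670 at 2 weeks. Voom gave 1027 (cross) and 1 (cross against DO) at 24 h, and 0 (pH) and 1 (non-additive) at 2 weeks. Its lowest quality weight at 24 h fell on control fish Mys25 (0.302). The surrogate variable gave 0 for pH at 2 weeks. The stricter filter gave 1 for the non-additive part at 2 weeks. Fits of only the groups compared gave 2 for DO at 12 h, and 1 (pH), 2 (cross against pH) and 16 (cross against DO) at 2 weeks. The mean over exposures gave 2623 features for 24 h against 12 h and 10897 for 2 weeks against 12 h, with more fish in the contrast.

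With the controls split into 2 and 2, so that fold changes shared no control fish, the correlations of pH with DO, pH with cross and DO with cross were -0.0516, -0.0709 and -0.117 at 12 h (sign reversed), 0.166, 0.199 and 0.297 at 24 h, and 0.0179, 0.00808 and 0.0462 at 2 weeks; the loss of the shared control fish is part of the construction.

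With each fish left out in turn, counts at 12 h ran from 0 to 2 (pH), 0 to 2 (DO), 0 to 0 (cross), 0 to 0 (cross against pH), 0 to 329 (cross against DO, highest without fish Mys7066) and 0 to 3 (non-additive). At 24 h they ran from 0 to 1 (pH), 0 to 0 (DO), 0 to 1019 (cross, highest without fish Mys25), 0 to 1 (cross against pH), 0 to 1 (cross against DO) and 0 to 0 (non-additive). At 2 weeks they ran from 0 to 933 (pH, highest without fish Mys54), 1 to 1 (DO), 0 to 0 (cross), 0 to 774 (cross against pH), 1 to 1 (cross against DO) and 1 to 766 (non-additive). In controls they ran from 12 to 2094 (24 h against 12 h, lowest without fish Mys28, highest without fish Mys25) and 2849 to 5139 (2 weeks against 12 h, lowest without fish Mys15, highest without fish Mys13). Effects that differ between times ran from 0 to 12 (pH), 0 to 5 (DO) and 0 to 985 (cross, all highest without fish Mys25).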

Other observations

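The scan for features with separate levels, and the distance tests without the pH fish and without fish Mys53, were chosen after results had been seen.

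TRINITY_DN45128_c3_g1, higher in control fish at 2 weeks than at 12 h, had 2 separate levels over the 44 fish: 13 fish were at 68.2 CPM or more and 31 at 4.22 CPM or less. The high fish were 4 of 4 controls, 2 of 4 cross, 0 of 4 DO and 0 of 2 pH fish at 2 weeks, 2 of 4 cross, 2 of 3 DO, 1 of 3 pH and 0 of 4 control fish at 24 h, and 2 of 4 cross fish and 0 of the other 12 fish at 12 h. The number of high fish thus did not rise from 12 h to 2 weeks in pH, DO or cross fish. In a scan of 34070 features, 4 were at or under 2 CPM or at or over 10 CPM in every fish, with at least 2 fish of each kind at every time. TRINITY_DN45128_c3_g1 was not among these 4. A hypothesis that the 4 may be alternative assembled forms of 1 gene could not be judged, since none of the 6 pairs had opposite states in all 44 fish and 0 shared a Trinity component.

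Exposure as a whole, tested on the distances between fish, gave a permutation p of 0.187 at 12 h, 0.229 at 24 h and 0.00300 at 2 weeks, where exposure held 29.0% of the squared distances and chance gives 23.1%. Without the pH fish the 2 week value was p = 0.114 by permutation, and exposure held 20.5% where chance gives 18.2%. Without pH fish Mys53, which leaves 1 pH fish, exposure held 27.5% where chance gives 25%. Both tests held fewer fish, and no other fish or group was left out. They therefore do not settle which fish carry the difference.

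The 340 features that differed between control fish at 12 h and 24 h were followed in exposed fish. A difference limited to those 8 control fish or their aquaria would leave exposed fish under 0.25 of the control difference, and they showed 0.359 (SE 0.0714, permutation p = 6e-05), with 307 of the 340 features (90.3%) of the same sign. This lies above 0.25 by less than 2 SE (the control difference taken as fixed), so the bound set in advance was not reached. The control fish may still account for part of the difference. Relative to the 12 h controls, the score of these features was 0.81 in control fish Mys25, 1.69 in fish Mys26, 1.78 in fish Mys27 and 2.14 in fish Mys28.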
